A study of Synechocystis sp. PCC 6803 with 32 samples.

How the data were processed

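RNA of Synechocystis sp. PCC 6803 was measured on 32 one-colour Agilent arrays, 2 for each of 16 groups, from 4 strains in 2 experiments. In the iron experiment (24 arrays), wild type and the IsaR1 deletion strain were sampled at 0, 3, 12, 24, 48 and 72 h of treatment with 100 µM desferrioxamine B. In the copper experiment (8 arrays), the IsaR1 overexpression strain and the empty-vector strain were sampled at 0 and 6 h of treatment with 2 µM CuSO4. Per the labels' protocols, cultures grew at 30 °C under 50 µmol photons per square metre and second, with 2 µg/ml gentamicin for the strains that carried a plasmid; the iron cultures were aerated and the copper cultures were shaken without aeration. Total RNA (2 µg) was labelled directly with Cy3, so no reverse transcription preceded hybridisation. The series text gives the 2 samples of a group as independent biological replicates and says that the wild-type iron arrays had been published before.

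The deposited scanner files hold one array each, as intensity values on a linear scale, written by Agilent Feature Extraction 10.7.3.1 with the protocol GE1_107_Sep09, per the file headers. The processed signal is the intensity after background subtraction by that software, per the file headers, and was not scaled between arrays. The deposited files also give, for each spot, flags for a signal well above background, for saturation and for outliers. The authors' series table gives a value per spot and array on a log2 scale, and all 32 columns have a median of 10.8 and nearly the same distribution, which is the form quantile normalization leaves. The background method behind the series table is not given in the sources used here; limma appears, without a version, in the submitters' processing notes. The table's differences between arrays ran in the same direction as those of the scanner values. No column of per-sample values was left without a sample.

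Each array has 42303 spots, of which 1417 are control spots, and the 20363 probes of the others belong to 8830 features, mostly as 2 spots per probe. The log2 of the deposited processed intensity was taken for the 40886 spots that are not controls, and the array's own 75th percentile was subtracted. Spots with an outlier flag were left out, spots of a probe were averaged, and probes of a feature were averaged. Features were kept where at least 1 probe was well above background on both arrays of at least 1 group of the experiment, which left 8282 features for the iron experiment and 8173 for the copper experiment. Among the features named below that passed the threshold and have more than 1 probe, probes of both signs were seen for 2 of 51 in the induction effect, 2 of 94 in the late strain difference and 4 of 103 at 24 h in wild type. A total of 914 probes share their sequence with another probe.

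Each contrast was tested on the log2 scale with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with the Benjamini-Hochberg adjustment over all features kept and a threshold of 0.05 for the adjusted p. The copper arrays and the iron arrays were fitted separately with 1 mean per group, and the late strain difference was fitted over the 12 arrays at 24, 48 and 72 h with terms for time and strain. That late fit takes the 12 arrays as independent. If the same cultures were sampled at several times, its p-values may be too small. The induction effect is the change from 0 to 6 h in the overexpression strain minus that in the empty-vector strain. Responses over time were tested with limma's F test over the 5 later times. The correlation across features of the induction effect and the late strain difference was tested with a two-sided permutation test of 100000 resamples, and overlaps of calls with Fisher's exact test, two-sided. Where a feature was not well above background on either array of a group, only a bound is given there: the brighter group's mean against the mean of, per array, the higher of the lowest signal among probes well above background and the feature's own signal. Fold bounds are ratios; every other change is a log2 difference with its standard error (SE). The arrays' number limits the precision.

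The arrays lie on 10 slides of up to 4 arrays, scanned on 9 days. Wild type and deletion strain lie on separate slides at 0, 3 and 12 h and share slides at 24, 48 and 72 h; all copper arrays of a time share a slide. Slide therefore cancels in the late strain difference, in the induction effect, in the strain contrasts at 0 and 6 h of copper, and in the difference of the change from 3 to 12 h, since each strain's 3 and 12 h arrays share a slide. For the strain difference at 0 h and for every change against 0 h, slide and group cannot be told apart.

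The array names genes by locus tag. The reference table (assembly ASM28445v1) matched 0 of the 3364 protein-coding features, so no symbol comes from it; symbols and functions were taken from general knowledge, as part of the gene lists, and other features keep their tag. No genome was used and no coordinates are given. IsaR1 is the feature NC-181, an assignment that also comes from general knowledge and not from the files.

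A total of 25 gene lists were tested: photosystem I, photosystem II, cytochrome b6f and soluble electron carriers, phycobilisome, ATP synthase, iron-sulfur cluster assembly, tetrapyrrole synthesis, iron uptake, the operon of the iron-stress chlorophyll protein and flavodoxin (isi operon), iron storage and Fur-family regulators, reported IsaR1 targets, flavodiiron proteins, carboxysome and Calvin cycle, inorganic carbon uptake, nitrogen assimilation, the NDH-1 complex, terminal oxidases and succinate dehydrogenase, antioxidant enzymes, high-light-inducible proteins and phycobilisome degradation, heat shock proteins and proteases, sigma factors, ribosomal proteins, copper response, type IV pili, and phosphate starvation. They hold 325 genes, of which 319 are on the array; the other 6 belong to the copper list. The 9 reported IsaR1 targets were chosen by the study partly on these arrays, and each of the suf genes, petF, hemA and sodB is also in another list. Lists were tested against all other features with camera (preset correlation 0.01) and again with an estimated correlation; fry tested whether a list's own genes moved one way on balance. The adjusted p of a list is over the 25 lists of a contrast. Counts of list members are given over all features tested and adjusted over the list alone.

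The design, the lists, the tests, the threshold and the rule for named genes were set before the data were examined. For the induction effect, the late strain difference and wild type at 24 h, the rule took the 10 highest and 10 lowest protein-coding features past the threshold that moved the same way in every replicate. In the same way it took the 3 highest and 3 lowest antisense or intergenic RNAs, and, without that condition, up to 4 members of each list with the smallest p. Moving the same way meant, for induction, that both induced arrays lay beyond all other 6 arrays; for the late difference, the same sign at 24, 48 and 72 h; and at 24 h in wild type, both arrays beyond both 0 h arrays. For the other contrasts it took the 3 highest, the 3 lowest and list members in the same way, and a gene named for one contrast may be given in others. Of features without a symbol, at most 2 that rose and 2 that fell are printed per comparison.

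Alternatives tried were quantile normalization, median centring, the 75th percentile over probes well above background on all arrays, normexp background correction (offset 50) with either scaling, the authors' table, no filter, a filter on every array, medians over probes, stricter thresholds, a trended and robust eBayes, slide or replicate number as a block, one fit over all 32 arrays, and leaving out each array in turn. Normexp took the deposited mean intensity and background, without 4 spots whose background exceeded them. The fit was tested on simulated data with 200 changed features. For the induction effect it recovered 14.9% of changes of 0.5, 70.2% of changes of 1 and 92.4% of changes of 2 on the log2 scale, with 4.84% false calls (8173 features). For the late strain difference the shares were 80.6%, 97.0% and 100%, with 5.13% false calls. The simulated noise was independent between arrays with the spread within groups, and simulated strain changes were the same at every time. A strain difference that varies with time was left out, so these shares may be too high for the real arrays. Figures were drawn with matplotlib 3.10.9, with pandas 2.3.3 in Python 3.11.15; tables were handled with the data.table package, version 1.17.8.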

Results

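Transcript levels of Synechocystis sp. PCC 6803, a unicellular cyanobacterium, were measured on 32 arrays. Their probes cover protein-coding genes, antisense RNAs, intergenic RNAs and 5' untranslated regions. IsaR1 is a small regulatory RNA that the cells make when iron is short. The iron experiment asked how wild type and a strain without IsaR1 responded over 72 h to 100 µM desferrioxamine B, a chelator that withdraws iron. The copper experiment asked what happened when IsaR1 was made without iron shortage. There, IsaR1 was expressed from the copper-induced petE promoter on a plasmid for 6 h after 2 µM CuSO4, and a strain with the empty plasmid was the control. Each of the 16 groups has 2 arrays, and their number limits the precision. Replicates of a group correlated at 0.976 to 0.999 across features, and none of the 16 pairs held identical values. The share of spots well above background was 66.9% to 92.8%, except on the second 0 h array of wild type, where it was 44.9%. No spot was saturated. Levels are log2 signals relative to the array's 75th percentile, and changes are log2 differences with the standard error (SE) of limma's fit.

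IsaR1 (feature NC-181, 1 probe) was read first, as a check of the labels. In wild type its level was 2.89 and 2.74 at 0 h, 4.74 and 4.67 at 3 h, 6.23 and 6.14 at 12 h, and 7.21 and 7.09 at 72 h of iron depletion. In the deletion strain it lay between −0.09 and 1.47 on all 12 arrays (mean 0.68 ± 0.41, SD), each rated well above background. The part of the gene that was deleted is not given in the sources used here, and a probe outside it would check nothing. Within the slides that held both strains, the deletion minus wild type difference of IsaR1 was −5.93 and −5.23 at 24 h, −5.58 at 48 h and −6.91 at 72 h. In the overexpression strain, copper took IsaR1 from 2.95 and 2.93 to 6.67 and 6.66. The empty-vector strain went from 2.80 and 2.73 to 1.87 and 1.92. The induction effect on IsaR1 was 4.59 (SE 0.09, adjusted p = 3.61e-06), and the strains differed by 0.18 before copper (adjusted p = 0.129).

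**Figure D1:**
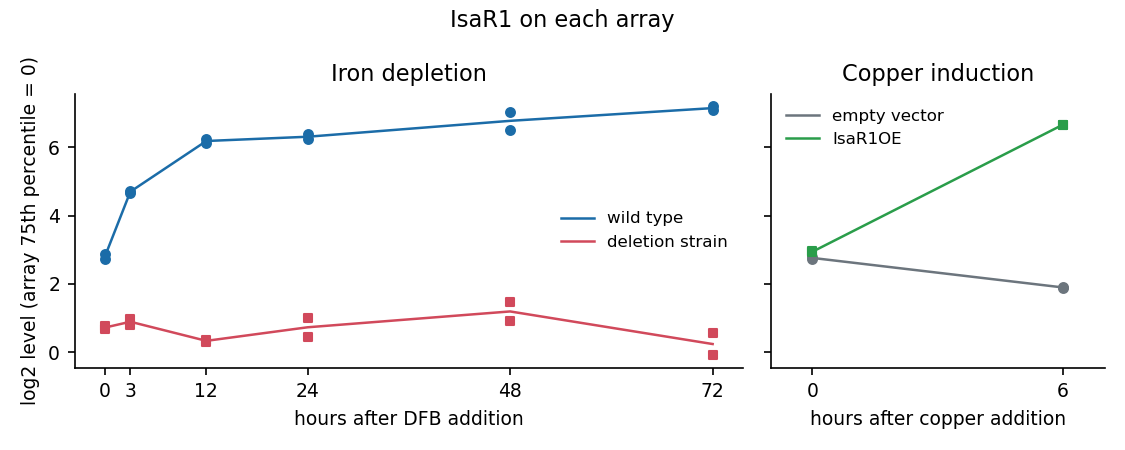
Level of IsaR1 (log2 signal relative to the array's 75th percentile) on each array against hours of iron depletion (one panel) and hours of copper treatment (the other panel); points are arrays and lines join the group means. Wild type climbs from 2.74 to 7.21, the deletion arrays stay at or below 1.47, and the induced overexpression arrays reach 6.67.

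Induction of IsaR1 lowered transcripts of ferredoxin, of 4 suf genes and of the cytochrome b6f complex. The induction effect is the change over 6 h in the overexpression strain minus that in the empty-vector strain, and genes that rose or fell in it did so relative to the empty vector. Expression of petF (ssl0020), the main ferredoxin, fell by 2.28 (SE 0.11, n = 2 arrays per group, adjusted p = 0.000765). No other protein-coding gene whose induced arrays lay below all 6 others fell further. Its level went from 3.56 to 1.98 ± 0.07 (SD, n = 2) in the overexpression strain and from 3.88 to 4.58 in the empty-vector strain. All 9 reported IsaR1 targets fell, also when adjusted over the list alone. Their median was −1.21 (adjusted p = 4.29e-10, and adjusted p = 0.102 with an estimated correlation). The study chose that list partly on these arrays, so its direction is not independent evidence. The list holds genes that build iron-sulfur clusters, of which sufC (slr0075) was at −1.73 (SE 0.12), sufD (slr0076) at −1.25 and sufS (slr0077) at −1.21. It also holds acnB (slr0665), aconitase, at −1.22, and ilvD (slr0452), dihydroxy-acid dehydratase, at −1.14. Iron superoxide dismutase, sodB (slr1516), was at −1.11 (SE 0.17, adjusted p = 0.0174) and hemA (slr1808), glutamyl-tRNA reductase, at −0.85. In the iron-sulfur cluster assembly list, 4 of 11 fell, all of them suf genes (1 rose and 4 fell adjusted over the list alone). That list did not pass its own test (adjusted p = 0.432).

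Of the 13 genes for cytochrome b6f and soluble electron carriers, 6 fell and none rose (the same adjusted over the list alone). Beside petF they included petB (slr0342) at −1.57 (SE 0.10, adjusted p = 0.00136), petA (sll1317) at −1.16 and petD (slr0343) at −1.13. The list passed (adjusted p = 0.00899), but not with an estimated correlation (adjusted p = 0.436). Among 23 photosystem II genes 3 fell (3 adjusted over the list alone). They were psbV (sll0258) at −1.02, the cytochrome b559 gene psbF (smr0006) at −0.60, and psbL (smr0007) at −0.55, a call that 10 of 22 other settings ended. That list's median was 0.01, its mean −0.10, and its test pointed up without passing (adjusted p = 0.961). The sign of its median turned under 5 of 8 other settings. Of 28 tetrapyrrole synthesis genes 3 fell (3 adjusted over the list alone), which were hemA, chlH (slr1055), a magnesium chelatase subunit, at −0.98 (SE 0.09) and chlN (slr0750) at −0.93. Its median was 0.01, its mean −0.07, and the test pointed up (adjusted p = 0.729). Outside the lists, slr0851, a type 2 NADH dehydrogenase, passed as lower (adjusted p = 0.00152), but it was not well above background in the induced strain at 6 h, and no size of its fall can be given. The antisense RNA slr0015-as1 fell by 2.29 (SE 0.09, adjusted p = 0.000225), and the intergenic RNA NC-402 rose by 1.03 (SE 0.16, adjusted p = 0.0174).

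A minority of chaperone and NDH-1 genes rose in the induction effect. For the heat shock list the median strain difference was larger in size before copper than at 6 h. The highest rise of a protein-coding gene whose induced arrays lay above all 6 others was that of slr0884, glyceraldehyde-3-phosphate dehydrogenase 1, at 1.98 (SE 0.14, adjusted p = 0.00167). Of 16 heat shock proteins and proteases, 5 rose and none fell (7 rose adjusted over the list alone). They included htpG (sll0430) at 1.09 (SE 0.23), a call that 11 of 22 other settings ended, dnaK2 (sll0170) at 0.87, groEL2 (sll0416) at 0.77 and groEL1 (slr2076) at 0.66. The list passed with a median of 0.36 (adjusted p = 2.04e-06, and adjusted p = 0.224 with an estimated correlation). In the strain contrast at 6 h alone, its median was 0.04, with 5 higher and 1 lower (adjusted p = 0.114). Before copper, its median was −0.29 (adjusted p = 2.8e-05, and adjusted p = 0.567 with an estimated correlation). Of 16 NDH-1 genes 5 rose (5 adjusted over the list alone), among them ndhC (slr1279) at 0.98 (SE 0.15) and ndhA (sll0519) at 0.89. The NDH-1 list passed (adjusted p = 1.84e-05), but 2 of 8 other settings ended the call, among them the estimated correlation (adjusted p = 0.436).

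Most genes of inorganic carbon uptake and flavodiiron proteins fell on copper in the empty-vector strain. Some of them, such as cmpA and flv4, fell by less in the overexpression strain. The bicarbonate transporter gene cmpA (slr0040) changed by −7.28 in the empty-vector strain and by −3.36 in the overexpression strain, an induction effect of 3.92 (SE 0.63, adjusted p = 0.02). The flavodiiron gene flv4 (sll0217) changed by −6.60 and by −3.20, an effect of 3.40 (SE 0.35, adjusted p = 0.00482). Of 13 carbon uptake genes 4 rose in the induction effect (6 adjusted over the list alone). Besides cmpA they were ndhF3 (sll1732) at 2.12, sbtA (slr1512), a bicarbonate transporter, at 1.79, and cmpB (slr0041), which lay below background in both strains at 6 h. The call was ended by 13 of 22 other settings for sbtA and 12 of 21 for cmpB. The list passed (adjusted p = 0.00914), but not with an estimated correlation (adjusted p = 0.476), and quantile normalization ended the call. Of 5 flavodiiron genes, flv4 and flv3 (sll0550, 0.47) rose, and 4 did adjusted over the list alone (list adjusted p = 0.00015, and adjusted p = 0.436 with an estimated correlation). For flv2 (sll0219) and sll0218, which passed only over the list alone, no rise is measured. At 6 h flv2 was well above background on no array of either strain, and sll0218 on 1 overexpression array only. The flv3 call was ended by 14 of 22 other settings.

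On copper 12 of 17 nitrogen assimilation genes rose in the empty-vector strain and 3 fell (list adjusted p = 0.0115, and adjusted p = 0.408 with an estimated correlation). The induction effect was negative for 3 of the 17 and positive for 1. Expression of nrtA (sll1450), of the nitrate transporter, rose by 3.65 and 0.80, an induction effect of −2.85 (SE 0.18, adjusted p = 0.00136). The effect was −2.91 (SE 0.27) for nirA (slr0898), nitrite reductase, and −2.76 (SE 0.49) for glnN (slr0288), a glutamine synthetase. For gifA (ssl1911), an inhibitor of glutamine synthetase, it was 1.15. These were the 4 of 17 that passed; adjusted over the list alone 3 rose and 10 fell. The list did not pass (median −1.43, adjusted p = 0.135). Before copper, nirA, nrtA and glnN had been higher in the overexpression strain by 1.63, 1.53 and 1.76, so that the strain contrast at 6 h alone held 43.9%, 46.3% and 36.3% of their effect. Of 9 sigma factors, sigI (sll0687) passed as lower, as 1 did adjusted over the list alone (list adjusted p = 0.473). At 6 h it was well above background on no induced array and on 1 empty-vector array, so no fall is measured, and 17 of 21 other settings ended the call. Among 6 antioxidant enzymes sodB fell (1 rose and 1 fell adjusted over the list alone). That list's median of 0.13 and upward test went with a mean of −0.01 (adjusted p = 0.342).

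No member passed limma's threshold in the other 13 lists. At an unadjusted p under 0.05 there were 1 of 12 for photosystem I, 1 of 13 for phycobilisome, 0 of 9 for ATP synthase and 3 of 19 for iron uptake. There were 0 of 2 for the isi operon, 2 of 7 for iron storage and Fur-family regulators, 3 of 19 for carboxysome and Calvin cycle and 4 of 8 for terminal oxidases and succinate dehydrogenase. The numbers were 1 of 6 for high-light-inducible proteins, 2 of 41 for ribosomal proteins, 1 of 7 for the copper response, 0 of 9 for type IV pili and 1 of 8 for phosphate starvation. Adjusted over the list alone, 1 high-light-inducible gene rose and no other member of these passed. The ribosomal list passed as a whole (median 0.07, adjusted p = 0.00899, and adjusted p = 0.624 with an estimated correlation). Of the other normalizations 4 ended that call, and 3 of 8 other settings turned the sign of its median. The adjusted p of the remaining lists was 0.0594 for copper response, 0.135 for iron storage, 0.143 for carboxysome and Calvin cycle, 0.153 for high-light-inducible proteins and 0.167 for terminal oxidases. It was 0.393 for type IV pili, 0.473 each for phycobilisome, ATP synthase and the isi operon, 0.491 for photosystem I, 0.729 for phosphate starvation and 0.809 for iron uptake. With quantile normalization the photosystem I, photosystem II, phycobilisome and nitrogen lists passed as lower (adjusted p = 0.00298, 0.00194, 0.00298 and 0.00693). The copper list then passed as higher (adjusted p = 0.0445), and these 5 calls were also made with normexp and in the series table.

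In all, 624 of 8173 features passed for the induction effect. Of these 147 rose and 477 fell, including 58 and 194 protein-coding genes, and 210 changed by at least 1. Slide cancels in this effect (624 with slide as a random block), and within slides the strain contrast called 1363 at 6 h and 548 at 0 h. The count depended on single arrays. It was 260 without the second 0 h empty-vector array, and 319 and 262 without the first and second 6 h empty-vector array. Without the second 0 h overexpression array it was 361, and without the first and second 6 h overexpression array 138 and 258. Quantile normalization gave 319, normexp 337 or 369 by scaling, and the authors' values 371. Directions were then more even, from 116 rising and 203 falling (quantile normalization) to 160 and 177 (normexp with the 75th percentile).

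After 6 h of copper the empty-vector strain differed widely from 0 h, and these changes cannot be told apart from slide. Expression of petE (sll0199), the copper protein plastocyanin, rose by 6.92 (SE 0.19, adjusted p = 2.24e-06). That of petJ (sll1796), the cytochrome used in its place when copper is short, fell by 5.13. In the copper list 4 rose and 3 fell (4 and 3 adjusted over the list alone; adjusted p = 0.406), with copM (sll0788) up by 3.84. Genes of light harvesting and energy conversion rose: 12 of 12 for photosystem I (median 1.57), 13 of 13 for phycobilisome (median 2.02) and 9 of 9 for ATP synthase (median 1.45). Their list adjusted p was 9.82e-06, 1.79e-06 and 9.82e-06 (adjusted p = 0.398 for each with an estimated correlation). Inorganic carbon uptake fell in 9 of 13 and rose in 3, with cmpB at least 148-fold lower. Flavodiiron genes fell in 4 of 5, with flv2 (sll0219) at least 154-fold lower. List adjusted p was 0.00956 and 0.000987 (adjusted p = 0.398 for both with an estimated correlation). Among all features, 2454 rose and 2751 fell in the empty-vector strain, and 2138 rose and 3152 fell in the overexpression strain. Before copper, 548 features differed between the strains (342 higher and 206 lower in the overexpression strain). Among them were 3 lower carbon uptake genes, such as cmpC (slr0043, −1.05), and 3 higher nitrogen genes. These lists' adjusted p was 0.00161 and 0.0414 (adjusted p = 0.585 for both with an estimated correlation).

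In wild type, 24 h of iron depletion raised the genes of iron uptake and of the iron-stress proteins. The isi operon rose in 3 of 3 members (3 adjusted over the list alone). Expression of isiB (sll0248), flavodoxin, rose by 6.44 (SE 0.37, n = 2 arrays per group, adjusted p = 4.29e-09), though it was well above background on only 1 of the 2 arrays at 0 h. The chlorophyll-binding protein gene isiA (sll0247) rose by 5.75 (SE 0.30) and isiC (sll0249) by 4.65. Of 20 iron uptake genes, 15 rose and 3 fell (the same adjusted over the list alone; median 1.33). The ferric iron binding protein genes futA1 (slr1295) and futA2 (slr0513) rose by 3.81 (SE 0.06, adjusted p = 3.54e-15) and 4.04. Of the genes that energise outer membrane transport, exbB1 (sll1404) rose by 5.22, with 1 of the 2 arrays well above background at 0 h. For exbD1 (sll1405) neither was, which makes it at least 12.0-fold higher. Over the 9 iron uptake genes well above background on all arrays of both times, 6 rose and 2 fell (median 0.74). Adjusted p of the isi and iron uptake lists was 0.000424 and 1.24e-08 (adjusted p = 0.25 for both with an estimated correlation). Expression of fur (sll0567), the iron-dependent repressor, fell by 0.95. The antisense RNA of isiA, IsrR-0-x on the array, fell by 7.17. Among genes without a symbol, sll1206 and slr1485 rose by 5.46 and 4.57, each well above background on 1 of the 2 arrays at 0 h.

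The reported IsaR1 targets divided in wild type at 24 h, with 5 higher and 4 lower (the same adjusted over the list alone; median 0.19, adjusted p = 0.697). Expression of petF fell by 0.92 (SE 0.07, adjusted p = 5.57e-08), that of sodB was at −1.09 and that of ilvD at −0.68, and sufB (slr0074) rose by 1.55 (SE 0.15). By 48 h petF stood at 1.14 ± 0.03 (SD, n = 2), from 3.86 ± 0.07 at 0 h. Inorganic carbon uptake genes fell in 9 of 13 and rose in 2 (3 rose and 9 fell adjusted over the list alone; median −3.49). Among them cmpC was at −5.69 (well above background on 1 of 2 arrays at 24 h) and ndhD3 (sll1733) at −4.05, and cmpB was at least 48.1-fold lower. Flavodiiron genes fell in 4 of 5 (4 adjusted over the list alone; median −5.94), with flv2 at −6.61 and flv4 at −5.94 (SE 1.06). Neither list passed as a whole (adjusted p = 0.201 and 0.0816), though fry did (adjusted p = 7.45e-05 and 2.41e-06), and the flavodiiron list passed with normexp and quantile scaling and in the authors' values (adjusted p = 0.046 and 0.0454). Of the carbon uptake and flavodiiron genes, 13 were lower in the deletion strain at 0 h. All 13 had fallen in wild type by 3 h (median −4.00), while 1 fell in the deletion strain (median 0.46). They also fell in the empty-vector strain on copper, without the chelator (13 of 13, median −6.60). Their fall in wild type is therefore not shown to be a response to iron depletion. Nitrogen assimilation rose in 11 of 17 and fell in 3 (the same adjusted over the list alone). Here nrtA was at 3.82, nirA at 3.04 and gifA at −3.37, and the list passed (median 0.59, adjusted p = 0.00013, and adjusted p = 0.25 with an estimated correlation). Of 16 NDH-1 genes 12 fell (12 adjusted over the list alone; median −0.86), for example ndhB (sll0223) at −1.86. The list passed (adjusted p = 0.0113, and adjusted p = 0.603 with an estimated correlation), and normexp with the 75th percentile ended the call. Ribosomal protein genes rose in 24 of 41 and fell in 2 (the same adjusted over the list alone; median 0.20). That list passed too (adjusted p = 2.65e-06, and adjusted p = 0.473 with an estimated correlation).

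The other lists did not pass in wild type at 24 h. Their counts of genes that rose and fell were the same adjusted over the list alone, unless a second pair is given. Photosystem I had 1 and 7, with psaE (ssr2831) at −0.57, photosystem II 5 and 6, cytochrome b6f and carriers 4 and 5, and phycobilisome 1 and 2. ATP synthase had 2 and 1 (2 and 0), with atpB (slr1329) at 1.08, iron-sulfur cluster assembly 5 and 3 (5 and 4), and tetrapyrrole synthesis 10 and 8. Over the 16 tetrapyrrole genes well above background on all arrays of both times, 6 rose and 5 fell. Detection ran against a fall for ho2 (sll1875), with 0 arrays at 0 h and 2 at 24 h, and for hemN (sll1876, 0 and 1). In later lists the same held for pfsR (sll1392, 1 and 2), sigI (1 and 2) and copS (sll0790, 0 and 2). There were 1 and 4 for iron storage and Fur-family regulators, 9 and 5 for carboxysome and Calvin cycle, and 1 and 6 for terminal oxidases, with cydA (slr1379) at −0.90. Antioxidant enzymes had 3 and 1, high-light-inducible proteins 4 and 2, with hliA (ssl2542) at 2.17, and heat shock proteins 7 and 3. The pairs were 2 and 7 for sigma factors, 0 and 5 for the copper response, with copM at −2.90, 4 and 3 for type IV pili, and 0 and 6 for phosphate starvation (0 and 7). Of the latter list only 3 of 8 genes were well above background on all arrays of both times, and 1 of these fell. Detection of pstS2 (slr1247), pstA2 (slr1249) and pstA1 (sll0682) ran against a fall, with 1 array at 0 h and 2 at 24 h. This list passed under 5 of 6 other normalizations (adjusted p = 0.0119 to 0.0419) and by fry (adjusted p = 5.38e-05). Normexp with the 75th percentile also called the lists of photosystem II, phycobilisome, ATP synthase, carboxysome and Calvin cycle, high-light-inducible and heat shock proteins higher (adjusted p = 0.000987 to 0.0435). Adjusted p of these lists ran from 0.0505 (high-light-inducible proteins and phosphate starvation) to 0.914 (photosystem II). Median, mean and test differed in sign for photosystem II (median −0.12, test up), cytochrome b6f (0.07, mean −0.09) and phycobilisome (−0.01, test up). They also differed for ATP synthase (−0.08, mean 0.13), tetrapyrrole synthesis (0.16, mean −0.03) and heat shock proteins (−0.01, mean 0.06).

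Over all later times, 7788 of 8282 features differed from 0 h in wild type by limma's F test, and 1813 rose and 3451 fell at 24 h. Slide and time cannot be told apart here, and 4564 passed among the 4716 features well above background on every array. At 72 h iron uptake had 16 of 20 higher than at 0 h (median 1.79, adjusted p = 9.26e-11, and adjusted p = 0.237 with an estimated correlation).

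The deletion strain also raised its iron genes. At 24 h, iron uptake rose in 16 of 20 and fell in none (median 1.90, adjusted p = 2.95e-18, and adjusted p = 0.072 with an estimated correlation), with futA1 at 3.15 and exbB1 at 6.63. The isi operon rose in 3 of 3 (median 5.99, adjusted p = 2.74e-06, and adjusted p = 0.121 with an estimated correlation). Photosystem I fell in 12 of 12 (median −0.88, adjusted p = 2.01e-07, and adjusted p = 0.204 with an estimated correlation). Phycobilisome fell in 12 of 13 (median −0.94, adjusted p = 1.89e-06, and adjusted p = 0.272 with an estimated correlation). The difference between the strains' 24 h responses was itself tested. It was negative for 11 of 12 photosystem I genes (median −0.66, adjusted p = 1.22e-05) and 11 of 13 phycobilisome genes (12 adjusted over the list alone; median −0.89, adjusted p = 2.7e-06). Both had an adjusted p = 0.365 with an estimated correlation. Slide does not cancel in the difference of responses, as the strains lie on separate slides at 0 h. There the median strain difference was already 0.59 for phycobilisome and 0.15 for photosystem I. On the shared slides of 24 h the medians were −0.44 and −0.36 for phycobilisome and −0.54 and −0.41 for photosystem I. For iron uptake the difference of responses was positive in 10 genes and negative in 1 (median 0.68, adjusted p = 0.0472, and adjusted p = 0.56 with an estimated correlation). Over the 9 of its genes well above background on all arrays of both times, 3 were positive and 1 negative (median 0.16). By 72 h the deletion strain's phycobilisome median lay at −2.80. Iron-sulfur cluster assembly had 10 of 11 genes higher than at 0 h by then (median 1.80, adjusted p = 4.97e-05, and adjusted p = 0.233 with an estimated correlation). Over all times, 7572 features changed in the deletion strain, and 6304 changed differently between the strains. Among the 4716 features well above background on every array, 4509 and 4004 did, and slide cannot be told apart from time in these counts.

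After 24 to 72 h of iron depletion, where both strains shared slides, transcripts of ferredoxin, iron-sulfur cluster assembly and superoxide dismutase were higher in the deletion strain. Those of the photosynthetic apparatus were lower. Expression of petF was higher by 1.35 (SE 0.14, adjusted p = 0.000184). At 72 h it stood at 1.41 ± 0.01 in wild type and 3.28 ± 0.13 in the deletion strain (SD, n = 2). That of sufD was higher by 1.67 (SE 0.22, adjusted p = 0.000754), of sufC by 1.69, of sufS by 1.66 and of sodB by 1.30 (SE 0.18, adjusted p = 0.000998). Of the 9 reported IsaR1 targets 7 were higher and none lower (8 higher adjusted over the list alone), with a median of 1.30. The list passed (adjusted p = 2.89e-05, and adjusted p = 0.62 with an estimated correlation), and again it is not independent evidence. The targets that did not pass were ilvD at 0.29 (adjusted p = 0.051) and hemA at −0.07. Iron-sulfur cluster assembly had 6 of 11 higher and 1 lower (6 and 2 adjusted over the list alone; adjusted p = 0.0404, and adjusted p = 0.62 with an estimated correlation). IsaR1 itself was lower, at −6.03 (SE 0.25, adjusted p = 2.38e-07).

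**Figure D2:**
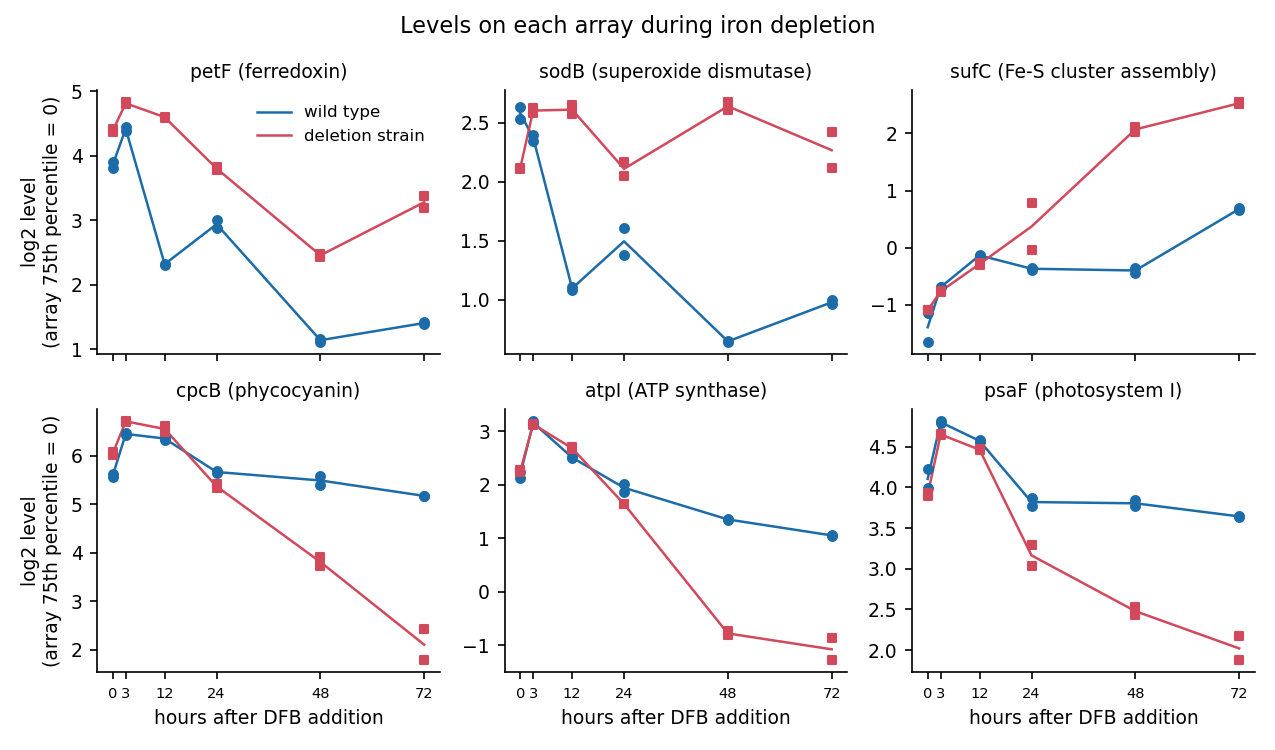
Levels (log2 signal relative to the array's 75th percentile) of petF, sodB, sufC, cpcB, atpI and psaF on each array against hours of iron depletion, in wild type and deletion strain; points are arrays and lines join group means. At 72 h petF averaged 1.41 in wild type and 3.28 in the deletion strain, and cpcB averaged 5.17 and 2.10.

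Photosynthesis genes of 4 complexes were lower in the late deletion strain. In photosystem I, 11 of 12 genes were lower (11 adjusted over the list alone; median −0.91). Among them psaF (sll0819) was at −1.20 (SE 0.14, adjusted p = 0.000401), psaK1 (ssr0390) at −1.14 and psaE at −0.77 (SE 0.06). The phycobilisome, the light-harvesting antenna, was lower in 13 of 13 (13 adjusted over the list alone; median −1.16). Its genes included cpcG2 (sll1471) at −2.50 (SE 0.60), cpcB (sll1577) at −1.68 (SE 0.36) and apcF (slr1459) at −0.73 (SE 0.08, adjusted p = 0.000292). ATP synthase was lower in 8 of 9 (9 adjusted over the list alone; median −1.17), with atpI (sll1322) at −1.52 (SE 0.27) and atpC (sll1327) at −1.22. Photosystem II was lower in 16 of 23 and higher in 1 (1 and 17 adjusted over the list alone; median −0.56), with psbO (sll0427) at −0.74 and psbZ (sll1281) at 0.94. Adjusted p of these 4 lists was 1.16e-06, 1.28e-06, 0.000114 and 9.17e-05 in that order (adjusted p = 0.62 for each with an estimated correlation). Carboxysome and Calvin cycle genes were lower in 11 of 19 and higher in 1 (1 and 13 adjusted over the list alone; median −0.38). The Rubisco subunit genes rbcS (slr0012) and rbcL (slr0009) were at −1.20 and −0.95, and the list passed (adjusted p = 0.000564, and adjusted p = 0.62 with an estimated correlation). The isi operon was lower in 3 of 3 (3 adjusted over the list alone; adjusted p = 0.0435, and adjusted p = 0.62 with an estimated correlation). There isiB was at −1.01 (SE 0.21) and isiA at −0.72, and 5 of 6 other normalizations ended the list's call.

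Other groups were higher in the late deletion strain. Terminal oxidases and succinate dehydrogenase had 5 of 8 higher (7 adjusted over the list alone; median 0.36, adjusted p = 0.000114, and adjusted p = 0.62 with an estimated correlation). These included the cytochrome oxidase genes ctaC (slr1136) at 1.00 (SE 0.09, adjusted p = 0.000124), ctaE (slr1138) at 0.68 and ctaD (slr1137) at 0.60. Ribosomal proteins had 17 of 41 higher (17 adjusted over the list alone; median 0.20, adjusted p = 1.16e-06, and adjusted p = 0.62 with an estimated correlation), with rpl1 (sll1744) at 0.89. The sigma factor sigE (sll1689) was higher by 1.72 (SE 0.10, adjusted p = 3.2e-06), and sigB (sll0306) and sigA (slr0653) were lower, at −0.66 and −0.35. Of 9 sigma factors 1 was higher and 4 lower (1 and 6 adjusted over the list alone; adjusted p = 0.327). The highest features without a symbol under the naming rule were slr7100 and slr2107, the latter at 2.99 (SE 0.58). Since slr7100 was not well above background in wild type at 48 h, it was at least 3.86-fold higher there. Among antisense and intergenic RNAs under the naming rule, the lowest after IsaR1 was slr1591-as1, at −4.35 (SE 0.15, adjusted p = 1.55e-07).

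In the remaining lists the late strain difference went both ways or did not pass; pairs of numbers are genes higher and lower, and the second pair is adjusted over the list alone. Cytochrome b6f and carriers had 2 and 5 of 13 (3 and 6; adjusted p = 0.886), with petC2 (slr1185) at 0.65 beside petF and petG (smr0010) at −0.47. Tetrapyrrole synthesis had 6 and 7 of 28 (6 and 7; adjusted p = 0.973), with hemF (sll1185) at −0.62. Iron uptake had 1 and 8 of 20 (1 and 8; adjusted p = 0.0876), with exbB1 at −0.70. Iron storage and Fur-family regulators had 1 and 3 of 7 (1 and 3; adjusted p = 0.327), with perR (slr1738) at 0.53 and fur at −0.52. Flavodiiron proteins had 0 and 1 of 5 (0 and 2; adjusted p = 0.618) and inorganic carbon uptake 0 and 1 of 13 (0 and 0; adjusted p = 0.973). Nitrogen assimilation had 0 and 2 of 17 (0 and 1; adjusted p = 0.271), with amt1 (sll0108), an ammonium transporter, at −1.19, a call that 11 of 28 other settings ended. NDH-1 had 0 and 4 of 16 (0 and 4; adjusted p = 0.327), and antioxidant enzymes 1 and 0 of 6 (1 and 0; adjusted p = 0.618). Heat shock proteins had 5 and 4 of 16 (5 and 6; adjusted p = 0.99), with hrcA (sll1670) at 0.56 and clpB1 (slr1641) at −0.64. The copper response had 2 and 1 of 7 (2 and 3; adjusted p = 0.978), and type IV pili 2 and 3 of 9 (2 and 3; adjusted p = 0.99), with pilA2 (sll1695) at 0.91. Phosphate starvation had 0 and 3 of 8 (0 and 5; adjusted p = 0.188). Of these 3, phoA (sll0654) and pstS2 were not well above background on every late array, and the probes of sphX (sll0679) had both signs. Of the 6 high-light-inducible proteins none passed limma's threshold (1 at an unadjusted p under 0.05; list adjusted p = 0.618). Median, mean and test differed in sign for tetrapyrrole synthesis (0.04, mean −0.03), carbon uptake (−0.06, test up) and antioxidant enzymes (−0.02, mean 0.17). They differed too for the copper response (−0.07, mean 0.05) and type IV pili (−0.11, mean 0.06).

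The median differences of the photosynthesis lists were larger at 48 and 72 h than at 24 h, when photosystem II was not called lower. On the slides of 24 h, the photosystem I median was −0.54 and −0.41, against −0.93 at 48 h and −1.40 at 72 h. Phycobilisome went from −0.44 and −0.36 to −1.48 and −1.63, and ATP synthase from −0.23 and −0.27 to −1.67 and −1.54. Photosystem II stood at 0.02 and −0.05 on the 24 h slides, with no gene past limma's threshold (3 at an unadjusted p under 0.05, 1 lower with slide as a block; list adjusted p = 0.435), then at −0.62 and −0.79. Reported targets stood at 0.34 and 0.56 on the 24 h slides, then at 1.36 and 1.29. Ribosomal proteins stood at 0.40 and 0.36 on the 24 h slides, then at 0.03 and 0.07. At 24 h 30 of 41 were higher (31 adjusted over the list alone; adjusted p = 7.44e-35, and adjusted p = 0.0342 with an estimated correlation). With slide as a fixed block the adjusted p over the late times was 3.66e-06 for photosystem I, 4.64e-06 for phycobilisome, 0.000329 for ATP synthase, 4.97e-05 for the targets and 2.04e-06 for ribosomal proteins. At 72 h nitrogen assimilation had 12 of 17 lower and 2 higher (median −1.80, adjusted p = 2.09e-05, and adjusted p = 0.17 with an estimated correlation), with nrtA at −3.60 and nirA at −2.59. At that time cpcG2 was at −5.14 and cpcB at −3.07.

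**Figure D3:**
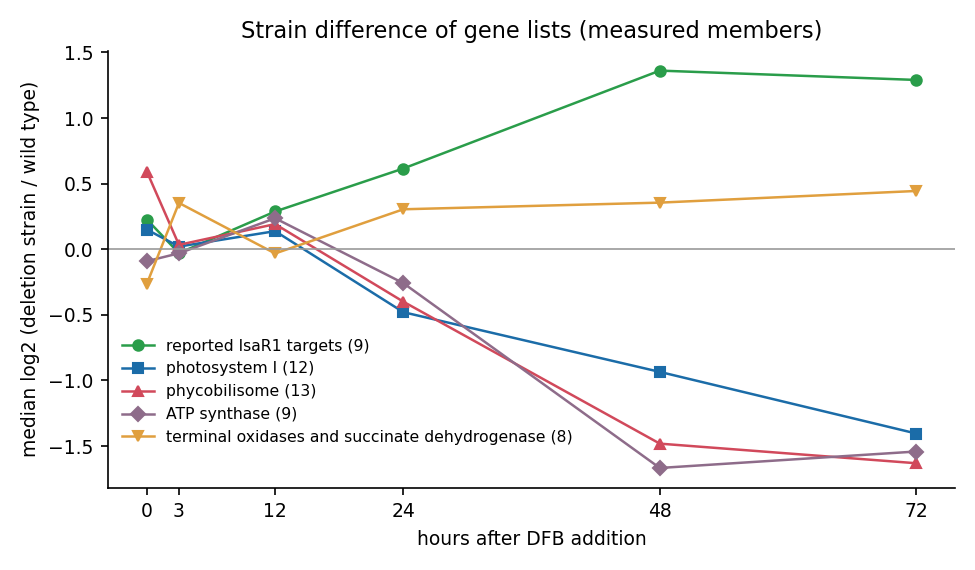
Median log2 difference between deletion strain and wild type (vertical axis) at 6 times of iron depletion (horizontal axis, hours) for 5 gene lists, with a line per list; the strains lie on separate slides at 0, 3 and 12 h. At 72 h the medians were −1.63 for phycobilisome, −1.54 for ATP synthase, −1.40 for photosystem I and 1.29 for the reported IsaR1 targets.

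In all, 2920 of 8282 features passed in the late strain difference. Of these 1330 were higher and 1590 lower in the deletion strain, including 743 and 545 protein-coding genes, and 305 differed by at least 1. The count takes arrays of different times as independent and may be too high if the same cultures were sampled at several times. With slide as a fixed block 3065 passed, and within single times 673, 3151 and 4277 at 24, 48 and 72 h (824 at 24 h with its slides as a block). Without the 72 h arrays, a choice made after seeing the data, 991 passed. With them, 1909 did among the 4716 features well above background on every array.

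At 0 h, before iron was withdrawn, genes of inorganic carbon uptake and the flavodiiron operon were far lower in the deletion strain, and nitrogen assimilation genes were higher. Each strain lies on a slide of its own there, so slide and strain are confounded. The 18 carbon uptake and flavodiiron genes had a median of −4.34, and 360 features of the same brightness one of 0.01 (quartiles −0.36 and 0.35). Of 13 carbon uptake genes 9 were lower and 3 higher (9 and 4 adjusted over the list alone; median −4.20). Of 5 flavodiiron genes 4 were lower and 1 higher (the same adjusted over the list alone; median −7.55). Examples are flv4 at −7.99 (SE 1.06), flv2 at −7.55 (SE 0.83), sbtB (slr1513) at −5.15, ndhD3 at −4.89 and cmpB, at least 38.6-fold lower. Neither list passed (adjusted p = 0.0752 for both), though fry did (adjusted p = 2.14e-05 and 1e-05). Nitrogen assimilation was higher in 11 of 17 and lower in 2 (12 and 2 adjusted over the list alone; adjusted p = 0.000469, and adjusted p = 0.443 with an estimated correlation). Here nrtA was at 3.01 (SE 0.12, adjusted p = 8.33e-11), nrtB (sll1451) at 2.87 and gifA at −3.03. Phycobilisome was higher in 10 of 13 (11 adjusted over the list alone; median 0.59, adjusted p = 0.000428, and adjusted p = 0.444 with an estimated correlation). NDH-1 was lower in 11 of 16 (12 adjusted over the list alone; median −1.11, adjusted p = 0.000469, and adjusted p = 0.444 with an estimated correlation). Iron uptake was lower in 14 of 20 and higher in 4 (median −0.82, adjusted p = 0.0392, and adjusted p = 0.472 with an estimated correlation). Dim features read lower as a whole, with a median of −0.54 in the dimmest of 4 brightness groups and 0.07 in the brightest. Over the 9 iron uptake genes well above background on all 0 h arrays the median was −0.08, with 4 lower and 3 higher. In all 4948 of 8282 features differed at 0 h, 2052 higher and 2896 lower in the deletion strain. Of the 4716 features well above background on every array, 3045 did. The balance of directions depended on scaling. It was 2760 higher and 2342 lower with quantile normalization, 2756 and 2395 in the authors' values, and 1806 and 4220 with normexp and the 75th percentile. The wild-type 0 h arrays had the lowest correlation of a replicate pair (0.976), and 503 features were more than 1 apart between them.

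At 3 and 12 h, with strains again on separate slides, 1911 and 3258 features differed. Iron uptake genes were lower in the deletion strain, 14 of 20 at 3 h and 17 of 20 at 12 h (medians −0.59 and −0.66). Their adjusted p was 2.65e-09 and 1.36e-06 (adjusted p = 0.191 and 0.312 with an estimated correlation). The isi operon was lower in 3 of 3 at 3 h (median −3.27, adjusted p = 0.000185, and adjusted p = 0.191 with an estimated correlation). The level of isiA was 3.16 in wild type and 0.02 in the deletion strain at 3 h, and 6.38 and 5.39 at 12 h.

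Slide cancels in the change from 3 to 12 h, since each strain's arrays of these times share a slide. Between the strains this change differed for ferredoxin, superoxide dismutase and some iron uptake genes. The difference was 1.88 (SE 0.10, adjusted p = 3.02e-08) for petF, whose level went from 4.42 to 2.32 in wild type and from 4.82 to 4.60 in the deletion strain. For sodB it was 1.29 (SE 0.13, adjusted p = 4.42e-05). Of the 9 reported targets, 4 differed upward and none downward (4 and 1 adjusted over the list alone; median 0.11, adjusted p = 0.0014, and adjusted p = 0.355 with an estimated correlation). For isiA the difference was 2.15 (SE 0.42, adjusted p = 0.00717), for exbD1 2.39 (SE 0.25) and for fhuA1 (sll1406) 2.01. Of 20 iron uptake genes 4 differed upward and 2 downward (5 and 2 adjusted over the list alone), and the list did not pass (adjusted p = 0.175). Carboxysome and Calvin cycle genes differed upward in 6 of 19 (10 up and 1 down adjusted over the list alone; adjusted p = 1.29e-05, and adjusted p = 0.166 with an estimated correlation). Cytochrome b6f and carriers did in 4 of 13, with 1 down (7 and 1 adjusted over the list alone; adjusted p = 0.000119, and adjusted p = 0.355 with an estimated correlation). In all 502 features changed differently, and the deletion strain's change minus that of wild type was positive for 214 and negative for 288. The count was 292 and 241 without the first and second wild-type 3 h array, and 254 and 225 without the first and second wild-type 12 h array. It was 327 without the second deletion 3 h array and 302 without the first deletion 12 h array.

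The last comparison asked whether induction and deletion moved the same features in opposite directions; no array is shared between them. Genes that fell on induction and were higher in the late deletion strain included petF (−2.28 and 1.35), sufC (−1.73 and 1.69), sufD (−1.25 and 1.67), sufS (−1.21 and 1.66), acnB (−1.22 and 0.85) and sodB (−1.11 and 1.30). The cytochrome b6f genes petB, petA and petD also fell on induction but were not called higher in the late deletion strain. Nor were ilvD and hemA. Of the 8105 features measured in both, IsaR1 left out, 118 fell on induction and were higher in the late deletion strain. Independent calls would give 74.6 (odds ratio 1.86, Fisher's exact test, two-sided p = 1.05e-07, adjusted over the 4 overlaps p = 4.19e-07). Fisher's test takes features as independent, but a gene and its 5' untranslated region can both be counted. The p-values of these overlaps may therefore be too small. The other opposite pair, 32 that rose on induction and were lower in the deletion strain, was not distinguishable from the 28.3 of independent calls (p = 0.459, adjusted p = 0.459, Fisher's exact test). Pairs of equal direction were fewer than from independent calls. There were 11 against 23.5 for higher in both (p = 0.00295, adjusted p = 0.00394, Fisher's exact test) and 63 against 89.7 for lower in both (p = 0.00104, adjusted p = 0.00209, Fisher's exact test). Under quantile normalization, both normexp settings, the authors' values and no filter on dim features, neither pair of equal direction passed at an adjusted p under 0.05. Across features, which are not independent replicates, Pearson's r was −0.0716 and Spearman's rho −0.0901 (permutation test, two-sided p = 1e-05 for both, the smallest it can give). With quantile normalization, both normexp settings and the authors' values, r lay between −0.0206 and −0.0019 and no longer passed (permutation p = 0.0639 to 0.863). Under these settings rho lay between −0.0554 and −0.0364 and still passed (permutation p = 1e-05 to 0.00124).

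**Figure D4:**
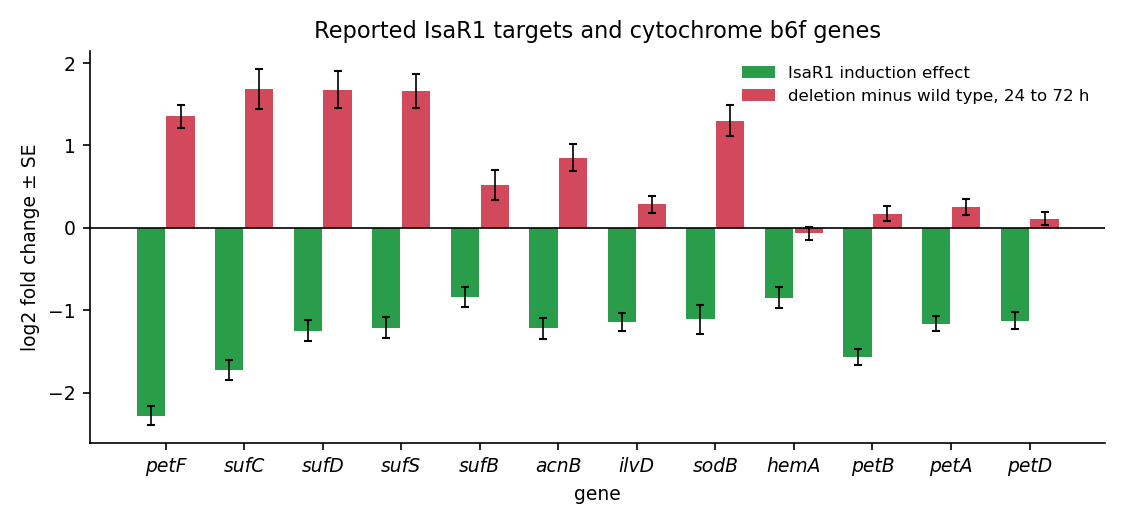
Log2 change of 12 genes on IsaR1 induction (6 h of copper, relative to the empty vector) and log2 difference of deletion strain to wild type at 24 to 72 h; bars are estimates and whiskers are SE of limma's fit. On induction petF fell by 2.28 and in the deletion strain it was higher by 1.35. Levels of hemA were at −0.85 on induction and at −0.07 in the deletion strain. The cytochrome b6f genes petB, petA and petD fell on induction and were not called higher in the deletion strain.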

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

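Among the tests below, those of the carbon uptake and flavodiiron lists and of the dim features at 0 h and that of the induction effect by direction were chosen after the result was seen. The results here are differences between strains in the same response, each from a test of the difference itself. In all, 6304 features differed between wild type and deletion strain in their response over time, 502 in the change from 3 to 12 h, and 624 between the vector strains in their copper response.

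For the genes named at 24 h of iron depletion, the deletion strain's response minus that of wild type was largest in carbon uptake and flavodiiron genes. It was 7.66 for cmpB (slr0041), 6.51 for sll0218 of the flavodiiron operon, 6.42 for flv2 (sll0219), 5.35 for cmpC (slr0043), 5.26 for flv4 (sll0217), 4.39 for ndhD3 (sll1733), 3.58 for cmpA (slr0040) and 3.48 for cmpD (slr0044). In wild type the genes flv2 and ndhD3 went by −6.61 and −4.05, and in the deletion strain by −0.19 and 0.34. Features without a symbol that differed likewise were slr0042 at 4.96 and slr0616 at 3.99. Since cmpB was not well above background in wild type at 24 h or in the deletion strain at 0 h, its value is no bound; cmpC was measured on 1 of 2 arrays in wild type at 24 h and flv4 on 1 of 2 in the deletion strain. For isiC (sll0249) the difference was 1.34, from lower levels in the deletion strain at 0 h (−4.74 against −2.51) and at 24 h (1.24 against 2.13). Values of 1.41 for exbB1 (sll1404), 1.32 for exbD1 (sll1405) and 1.97, 1.40 and 0.76 for 3 further coding features rest on levels at 0 h in wild type that were well above background on no array for exbD1 and on 1 of 2 for the others, so they do not show a larger rise. IsaR1 differed by −3.49, the antisense RNA IsrR-0-x by 1.64 and another antisense RNA by −0.86.

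The first pattern is the strain difference at 0 h, which sets these values. A raised background on the wild-type 0 h arrays as the whole cause is argued against, since of 4 equal groups by brightness the brightest had 62.5% called and the dimmest 61.1% (a gap of 1.4 percentage points). For dim features it stays open and has support: features lower in the deletion strain were 53.1% of the dimmest and 26.3% of the brightest group (−26.75 percentage points), and the median difference was −0.54 and 0.07. For the 18 carbon uptake and flavodiiron genes, features of the same brightness had a median 4.35 above theirs (0.01 against −4.34), which argues against slide as their whole cause. Of the 13 that were lower, 6 were well above background on every iron array; for these a lasting effect of the size seen at 0 h is argued against, since their median difference was −4.69 at 0 h and no later one exceeded 1.05 in size (−1.05 at 24 h, 0.86 at 72 h). For the other 7, at background on some later arrays, a lasting effect cannot be told apart from none. Their median difference was −7.31 at 0 h, and the later one largest in size was 2.24, at 72 h, of opposite sign. An effect that shows only while wild type expresses these genes highly was not tested. For the other features slide stays open, because the strain difference at 0 h did not follow that within slides later (r = −0.082 across features), and the state of the cultures at 0 h was not tested.

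Another pattern is the induction effect on nitrogen assimilation and carbon uptake genes, of which nrtA, nirA and glnN also differed between the vector strains before copper. Over the 8 genes of these lists that passed, the strain contrast at 6 h alone held a median of 63.7% of the effect, against 91.2% over the 9 reported targets (76.8% to 131%). The shares were 46.3% for nrtA, 43.9% for nirA and 36.3% for glnN, and 81.1% for cmpA, 85.4% for ndhF3 and 93.5% for sbtA. That median decides nothing, since genes that rose and fell part here. For the 4 that rose and were measured at 6 h (gifA besides these), the share was 87.6% in the median (81.1% to 93.5%) and each passed at 6 h, which argues against the difference at 0 h as its cause. For the 3 that fell the share was 43.95%, so the difference at 0 h holds the larger part, though nrtA and nirA also passed at 6 h. For cmpB, at background in both strains at 6 h, nothing can be said. Whether the cultures' nitrogen or carbon supply differed was not tested.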

How the results depend on the processing

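Filters on features bright at 0 h of wild type and the late comparison without 72 h were chosen after seeing the data. No named gene or gene list call reversed. For 55 of 116 features named in the induction effect and 59 of 119 in the late strain difference, the call was the same under every setting. The call was lost at least once for 36 and 48 of them in turn and for 8 of 110 in wild type at 24 h, and gained for 25, 12 and 1. The induction effect (624 features, 23.6% rising) gave 319 with quantile normalization (36.4% rising), 337 and 369 with normexp at the 75th percentile and quantile scaling (47.5% and 40.4%), 371 in the authors' values (38.5%) and 1363 in the 6 h contrast alone; the cause was not tested. Leaving out single arrays gave 138 (first 6 h overexpression array) to 672. The others that moved it by over 1.5 times were the second 0 h overexpression array (361), the second 6 h one (258), the second 0 h empty-vector array (260) and the first and second 6 h ones (319 and 262). The photosystem I (−0.17 to −0.35), photosystem II (−0.02 to −0.14), phycobilisome (−0.25 to −0.44) and nitrogen (−1.01 to −1.43) lists became called lower and copper response (0.18 to 0.26) higher under quantile, normexp and the authors' values, where the ribosomal call was lost (adjusted p = 0.624 to 0.811). The adjusted p of the reported targets ranged from 4.41e-17 to 0.102.

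Requiring a signal well above background on every array left 4716 of the 8282 iron features to test. It gave 1909 for the late strain difference and 3045 for 0 h. The responses of wild type and deletion strain gave 4564 and 4509, and their difference 4004. Features bright on both wild-type 0 h arrays (4851 tested) gave 3136, 4689, 4624 and 4109 for the last 4 of these. A change of at least 1 as well gave 210 for induction, 305 for the late difference, 1266 for 0 h, 110 for the change from 3 to 12 h, 3555 and 3075 for the responses and 3252 for their difference. An adjusted p under 0.01 gave 1.1e+02 for induction, 1437 for the late difference and 208 for the change from 3 to 12 h. Without the 72 h arrays 991 passed in the late difference, 860 of them shared with the 2920. Leaving out single arrays gave 2091 to 3384 for the late difference, 4008 to 5248 at 0 h, 7577 to 8040 and 7314 to 7500 for the responses and 5751 to 7056 for their difference. The change from 3 to 12 h (502) fell to 225 to 340, with 292 and 241 without the first and second wild-type 3 h array, 254 and 225 without the 12 h ones, 327 without the second deletion 3 h array and 302 without the first deletion 12 h array. A lone array is assumed to vary like the other groups. Slide as a random block gave 624 for induction, 2871 for the late difference, 4600 at 0 h and 553 for the change from 3 to 12 h.

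Scaling moved the share of higher calls from 45.5% to 34.2% (normexp, 75th percentile) and 52.7% (75th percentile over probes well above background) for the late difference, from 41.5% to 54.1% (quantile) and 30.0% (normexp, 75th percentile) at 0 h, from 42.6% to 54.6% (median centring) and 33.3% (75th percentile over probes well above background) for the change from 3 to 12 h and from 34.4% to 49.0% (quantile) and 23.8% (normexp, 75th percentile) at 24 h in wild type. There the median of all features was −0.18, and −0.03 and −0.30 under these settings. Pearson's r of induction and deletion (−0.0716) no longer passed with quantile (−0.0137), normexp (−0.0206 at the 75th percentile, −0.0030 with quantile) or the authors' values (−0.0019), while Spearman's rho still did; the cause was not tested. The overlap of features down on induction and up in the deletion strain held 118, and 51 to 145 under the other settings, with a p of at most 1.42e-05 in each (Fisher's exact test). That test takes features as independent, which they are not.

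Replicate numbers were not used to pair samples across times in the main fits. Deviations of same-numbered arrays correlated at −0.17 to 0.10 in the induction effect and −0.20 to 0.66 in the late difference, with 3 of 15 pairs over 0.1. In the responses over time they ran from −0.28 to 0.21 in wild type (3 of 15 over 0.1) and from −0.08 to 0.26 in the deletion strain (6 of 15 over 0.1, none below −0.1). In the change from 3 to 12 h they ran from −0.15 to 0.18. Such correlations cannot show whether the same cultures were sampled at several times. The 0.66 belongs to 24 h, where the number is the slide; with it as a block, added after seeing the data, 824 passed at 24 h (673 without, 671 shared). With the replicate block, induction called 370, the late difference 2731, 0 h 4971 and the change from 3 to 12 h 501. Signal over background limits the dimmest features, above all on the second 0 h array of wild type.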

Other observations

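The test of chance splits and those of the photosynthesis lists were chosen before their results were seen. Several gene groups moved in contrasts not yet described. After 3 h of iron depletion, 12 of 12 photosystem I genes, 13 of 13 phycobilisome genes and 9 of 9 ATP synthase genes were higher than at 0 h in wild type, with medians of 0.87, 1.36 and 1.26 (adjusted p = 1.74e-05, 1.89e-06 and 1.74e-05, limma's camera). None of these 3 calls held with an estimated correlation (adjusted p = 0.285 for each). In the deletion strain the same counts rose by 3 h, with medians of 0.74, 0.66 and 1.21. Slide cannot be told apart from time in these values. On copper, the empty-vector strain lowered 13 of 16 NDH-1 genes (2 rose; median −1.22, adjusted p = 0.0015, and adjusted p = 0.398 with an estimated correlation). It also lowered 6 of 6 high-light-inducible and phycobilisome degradation genes (median −1.75, adjusted p = 0.00181, and adjusted p = 0.398 with an estimated correlation).

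At 48 h all 6 high-light-inducible and phycobilisome degradation genes were lower in the deletion strain than in wild type on the same slide (6 adjusted over the list alone; median −1.06, adjusted p = 0.000908, and adjusted p = 0.25 with an estimated correlation). Expression of hliB (ssr2595) was at −2.42 (SE 0.13), against 0.09 at 24 h and −0.17 at 72 h, and that of hliA (ssl2542) at −1.84, against 0.46 and −0.01. The gene ftsH2 (slr0228), for a membrane protease, was at −1.04 at 48 h, 0.21 at 24 h and −0.43 at 72 h. By contrast sigE (sll1689) was higher in the deletion strain at all 3 times, by 1.35, 1.86 and 1.95.

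A further pattern is the lower level of photosystem I, phycobilisome and ATP synthase genes in the late deletion strain, a median of −1.13 over 34 genes. The scaling of the arrays is argued against, since under 6 other scalings the median rose no higher than −1.02. A shift of all bright features is argued against too, as 552 features of the same brightness had a median of −0.12, 1.01 above that of the lists, and no probe of these genes was saturated. The strains shared slides, and slide as a block left the calls. An effect of the lost IsaR1 and a different pace of growth or iron use in the deletion strain both remain as hypotheses that were not tested; the drop could follow from either.

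For the count of the late strain difference, 100 of the ways to part the 12 arrays within times were drawn, and only 1, the real one, gave as many as 2920 features. The highest other was 2071, a split that parts the strains one way at 2 of 3 times. Of the others 92 called none, and the 4 that called most all parted the strains one way at 2 times. If the arrays of a time are exchangeable, a chance parting is therefore unlikely to give this count. Most other draws put arrays of the same strain and time apart, though. Draws besides the real one that kept them together at all 3 times called 572, 13 and 0 features. Those are too few to judge whether whole groups would differ this much by chance. The splits take the arrays of a time as exchangeable and cannot test whether cultures were shared between times.

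The antisense RNA slr1591-as1 lay between 2.23 and 4.80 on the 12 wild-type arrays and between −1.84 and 0.86 on the 12 deletion arrays. On the empty-vector arrays it lay between −3.47 and −1.50 and on the overexpression arrays between −2.53 and −1.30, with an induction effect of 0.61 (adjusted p = 0.248). In the deletion strain at 72 h, 12 of the 18 carbon uptake and flavodiiron genes were more than 1 higher in the second array than in the first (median 2.45, against −0.07 over all features).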
